A study of Danio rerio with 4 samples.

How the data were processed

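Single-cell RNA sequencing was analysed from 4 libraries of zebrafish larvae that carried a Gal4 driver under the control of pdgfrb and a UAS reporter for a bacterial nitroreductase fused to the red fluorescent protein mCherry. Nitroreductase turns metronidazole into a toxic product, so that cells that make the enzyme are killed when the drug is added. Per the labels' protocols, larvae were kept at 28.5 °C and received metronidazole in 0.25% DMSO, or 0.25% DMSO alone, from 2 days post fertilization (dpf). The final concentration is stated as 2 nM, far below the doses commonly used with nitroreductase, and whether that unit is right was not settled. The trunk over 4 somites was taken at 4 dpf, 24 h after a spinal cord lesion, dissociated with 0.25% trypsin-EDTA and sorted for viable cells with calcein blue. Libraries were made with the Chromium Single Cell 3' kit and sequenced on an Illumina NovaSeq. The labels name 2 control libraries (DMSO) and 2 ablated libraries (metronidazole), numbered 1 and 2 in each group. They do not say whether the 2 libraries of a group came from separate pools of larvae. The p-values of gene and share tests thus measure the spread between these samples, which may be technical.

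The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, 1 matrix per library and not normalized. The matrices were written by Cell Ranger 6.0.1, per the file headers, and the genome build was GRCz11 with Cell Ranger 7.1, per the submitters' processing notes; which version made the counts was not settled. The feature list held 30423 genes, the same in all 4 libraries, with added entries for Gal4ff (0 UMIs in every library) and EGFP, and no entry for mCherry or the nitroreductase. The barcodes were those that the authors had already called as cells. The deposited matrices held 53333688 and 42811944 UMIs in control 1 and 2 and 61917532 and 52501896 in ablated 1 and 2. No genome was used here.

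Barcodes with at least 500 UMIs, at least 300 genes and at most 20% of UMIs on the 13 mitochondrial genes were kept. The lowest UMI count of a deposited barcode was 1055 in control 1, 724 in control 2, 512 in ablated 1 and 500 in ablated 2, so the libraries had been called at different depths before this filter. The filter removed 172 and 350 barcodes from control 1 and 2, and 1264 and 1001 from ablated 1 and 2. Doublets were treated by leaving out the barcodes with the highest Scrublet scores, 0.8% per 1000 barcodes, which came to 12.1%, 5.68%, 9.55% and 6.87% of the 4 libraries in the same order. There remained 13324 and 6703 control cells and 10791 and 7997 ablated cells, with medians of 1813.5, 1576, 850 and 1637 UMIs.

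Cells of all libraries were clustered together with scanpy 1.11.5 (2000 variable genes, 40 principal components, 15 neighbours, Leiden resolution 1 with igraph 0.11.9), leaving pdgfrb, the reporter entries and mitochondrial genes out of the genes used. Cell class names rest on marker lists for 33 classes, of which 696 of 724 symbols matched the feature list. A cluster was named when at least 3 markers of a class were among its 50 leading genes (log2 fold of at least 2, detected in at least 10% of its cells, with a pseudocount of 10 CPM). It also had to hold fewer markers of any other class there and among its 10 leading genes (where 0 markers of every class were allowed, as in clusters 15 and 33), and at most 90% of its cells could come from 1 library. These naming thresholds were set after the data had been seen; the marker lists had been fixed before. Cells in clusters without a name made up 43.0% and 50.8% of control 1 and 2, and 61.3% and 49.5% of ablated 1 and 2, and such clusters were compared by number. All class names below are short for "-like" classes, rebuilt here from markers. Clusters 3, 5 and 9, large clusters with no class and medians of 1398, 673 and 1532 UMIs, held 31.0%, 29.6%, 42.3% and 24.0% of the kept cells. Control 1 gave most cells of clusters 3 and 9 (2210 of 2473 and 1799 of 1833) and few of cluster 5 (120 of 8293). The macrophage and fibroblast classes were clustered again on their own (1000 variable genes, 20 components, resolution 1, and 0.5 as an alternative).

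UMI counts were summed per library over all kept cells (whole tissue) and over each class with at least 20 cells in every library, which gave 26 classes. Sums were tested with edgeR 4.0.16 (quasi-likelihood test with robust estimation, TMM scaling, its default filter on low counts, prior count 2) in R 4.3.3, control against ablated, with Benjamini-Hochberg adjustment over the genes of each fit and a threshold of 0.05. All tests were two-sided. Levels are given as CPM, the counts of a gene scaled to a common library size, on TMM-scaled sizes unless said otherwise, and log2 changes as ablated over control. Shares of cells per class were tested with edgeR on cell numbers, with the number of kept cells as library size, beside an exact permutation test, which cannot go below p = 0.333 with 2 libraries against 2. Intervals on shares of cells in 1 library are exact binomial 95% intervals and cover counting error only. To compare shares of cells with a UMI across depths, cells were also thinned to 1000 UMIs. Where a group had 0 UMIs of a gene, the fold is a lower bound against 3 UMIs over that group.

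Gene lists for 23 processes, of which 764 of 782 symbols matched, were tested with camera (limma 3.58.1, preset correlation 0.01) in whole tissue and each class where at least 5 members passed the filter, with adjustment over all lists and classes. Camera compares a list with the other genes of the same class, so a scaling factor that moves all genes alike does not move its call. With the preset correlation its p-values rest on an assumed correlation between genes. They are too small where the members of a list vary together more than that. The genes named were chosen by a rule. For whole tissue and each of the 7 leading classes, it took the 12 genes that rose most and the 12 that fell most among those past the threshold with a mean of at least 20 CPM. Where fewer than 6 genes passed, it took the 10 genes with the smallest p, as values. For the other classes it took up to 3 genes in each direction, and for each gene list up to 4 members past the threshold, or up to 2 as values where none passed. Genes with a clone or contig name were counted and not named, except zgc:158463 and LOC110438439, which were singled out after their values were seen. For 1 gene that this rule would name, the result is not reported.

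The analysis steps were tested on simulated data: negative binomial counts were drawn from the means, dispersions and library sizes of the real sums, with 200 genes changed. In whole tissue (21473 genes), 23% of the genes changed 2-fold and 98% of those changed 4-fold were called, with 11 false calls. In the fibroblast class (9793 genes) these shares were 27% and 97% with 3 false calls, in cluster 18 (10163 genes) 39% and 100% with 8, and in the macrophage class (10925 genes) 45% and 99% with 13. These shares hold for the simulated counts only. In the real whole-tissue sums cst14b.2 (log2 change -4.9) and rhcgl1 (2.44) were not called by edgeR (adjusted p = 0.73 for each). The absence of a call there thus does not exclude a 4-fold change, although the value of cst14b.2 may rest mainly on control 1.

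The tests, samples, lists, the rule for named genes and most alternative settings were fixed before the data were examined. Those settings were DESeq2 1.42.0, RLE size factors in edgeR, no filter on low counts, the replicate number as a block, each library left out in turn, no doublet removal, a stricter cell filter (1000 UMIs, 10% mitochondrial), other denominators and resolutions for shares (Leiden 2), and camera with an estimated correlation or fry for lists. A fit without 1 library sets 1 library against 2 and takes its spread from the group of 2 alone, so its calls do not show that a result is stable. Alternatives added after the data had been seen were library totals without TMM, edgeR without robust estimation, and leaving out the 2 abundant loci or clusters 3, 5 and 9. Pairs of libraries were compared for duplication: the chi-square of their counts per degree of freedom was 171 for the 2 control libraries, 148 for the 2 ablated libraries and 289 to 496 across groups, so no library was a copy of another. Numbers were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.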

Results

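The series measured gene expression in single cells of the zebrafish larval trunk, 24 h after a spinal cord lesion, in larvae treated with DMSO (2 control libraries) or with metronidazole to deplete pdgfrb-expressing cells (2 ablated libraries). The kept cells numbered 13324 and 6703 in control 1 and 2 and 10791 and 7997 in ablated 1 and 2, with 49607462, 40918609, 59370813 and 49246088 UMIs. The clusters covered neurons, ependymo-radial glia (the stem cells that line the spinal canal), fibroblasts, mural cells (the contractile cells around vessels), muscle, notochord, skin, blood and immune cells, and the depth per cell differed widely. Erythroid cells had a median of 2215 UMIs in control 1 and of 32473, 34503 and 39942 in control 2, ablated 1 and ablated 2. Haemoglobin genes took 3.58%, 4.24%, 7.47% and 2.59% of the UMIs in the same order.

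No change in the level of pdgfrb, the receptor whose promoter drove the nitroreductase, passed the threshold in whole tissue. It stood at 9.01 and 13.6 CPM of the library totals in control 1 and 2, and at 12.2 and 12.7 CPM in ablated 1 and 2 (11.3 ± 3.25 against 12.4 ± 0.337, SD, n = 2). The edgeR log2 change on TMM-scaled sums was -0.09 (SE 0.23, adjusted p = 0.977), and its sign turned to 0.14 with library totals, to 0.17 without control 2 and to 0.0027 without ablated 2. Cells with a pdgfrb UMI made up 2.83% (95% interval 2.55 to 3.13) and 5.88% (5.33 to 6.47) of control 1 and 2, and 4.81% (4.41 to 5.23) and 5.71% (5.22 to 6.25) of ablated 1 and 2. With cells thinned to 1000 UMIs, which left out 0, 1776, 6027 and 3201 cells, these shares were 1.46%, 2.98%, 2.69% and 2.11%. In erythroid cells, which should lack the gene, the shares without thinning were 1.64%, 0.885%, 0.719% and 0.957%. Erythroid cells of control 2, ablated 1 and ablated 2 were far deeper than other cells, so these shares are not a background for the thinned ones. In the classes with the highest pdgfrb levels no change passed the threshold. Fibroblasts had 93.0 and 117 CPM in the control libraries against 102 and 93.5, mural cells 90.6 and 76.4 against 70.0 and 85.4, and cluster 18 67.7 and 61.0 against 55.2 and 53.8, each as CPM of the class totals. On the TMM scale pdgfrb had a log2 change of -0.51 in fibroblasts (adjusted p = 0.364) and -0.51 in cluster 18 (adjusted p = 0.283), and the share of thinned mural cells with a UMI was 11.5% ± 0.315 and 8.47% ± 0.0165 (exact permutation p = 0.333). The labels state a final metronidazole concentration of 2 nM and the features hold no entry for the nitroreductase or mCherry, so how far the depletion went is not known from these libraries. Since the targeted gene was not called lower in whole tissue, "control" and "ablated" below stand for the libraries labelled so, and every direction is between libraries labelled ablated and libraries labelled control.

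**Figure D1:**
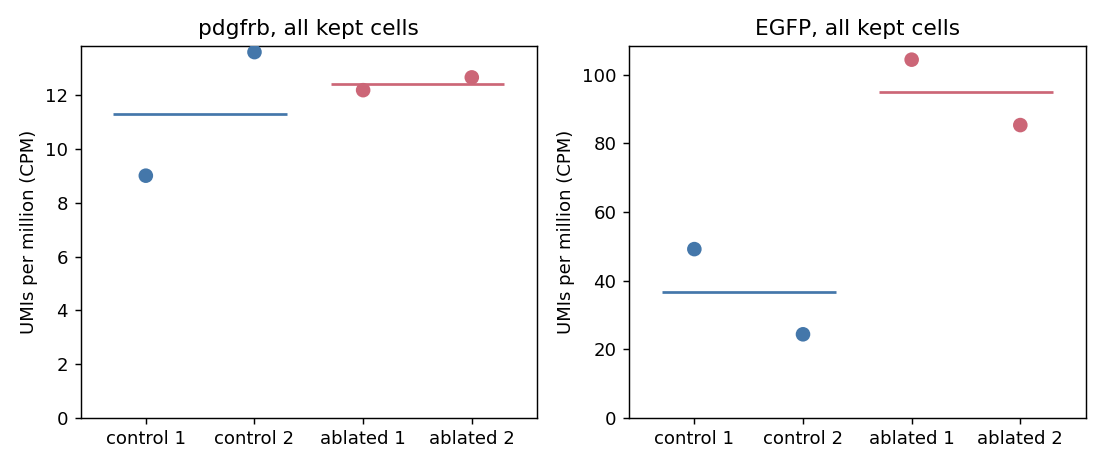
Levels of pdgfrb (left) and of the EGFP entry of the feature list (right) over all kept cells of each library, in CPM of the library totals; points are libraries and lines are group means. The pdgfrb points range from 9.01 to 13.6 CPM with overlapping groups, while EGFP lies at 24.3 and 49.2 CPM in the control libraries and at 85.3 and 104 CPM in the ablated ones.

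No change in the share of the classes with the highest pdgfrb levels passed the threshold, and with 2 libraries per group this does not show that the shares were alike. Fibroblasts made up 4.48% ± 3.16 of control cells and 5.64% ± 1.01 of ablated cells (SD, n = 2), a log2 ratio of 0.33 (SE 1.07, edgeR adjusted p = 0.959) that turned to -0.25 without control 1 and was 1.33 without control 2. Mural cells made up 2.27% ± 1.51 and 2.71% ± 0.337 (log2 ratio 0.26, -0.30 without control 1 and 1.17 without control 2), and fin fold mesenchyme 0.967% ± 0.6995 and 1.27% ± 0.0794. Cluster 18 was led by the matrix genes thbs4b, cilp and fmoda and held 6 fibroblast markers among its leading genes. It made up 2.14% and 3.595% of control 1 and 2 and 5.004% and 5.715% of ablated 1 and 2 (log2 ratio 0.90, SE 1.02, adjusted p = 0.959). Of immune cells, macrophages were at 2.995% ± 0.659 and 2.82% ± 0.773, and neutrophils at 4.50% ± 4.13 and 2.16% ± 0.0960. Neutrophils had a log2 ratio of -1.06, and of 0.45 without control 1. Neurons were at 5.67% ± 5.85 and 6.62% ± 2.12, ependymo-radial glia at 2.85% ± 1.96 and 3.602% ± 1.25, periderm at 3.70% ± 0.196 and 5.43% ± 0.373, and pronephros at 1.08% ± 0.238 and 0.392% ± 0.188.

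None of the 36 classes and clusters had a changed share by edgeR, and 2 (clusters 9 and 26) had an unadjusted p under 0.05. Without control 2 there were 6, the only library whose loss gave any. The smallest p of the exact permutation test is 0.333, so it could not pass the threshold. Clusters 9 and 26 held 1799 and 114 cells of control 1. They held 11 and 0 of control 2, 17 and 0 of ablated 1, and 6 and 0 of ablated 2, so nearly all their cells came from control 1. The spread between the 2 control libraries was wide, from 2.24% to 6.71% for fibroblasts, and the share of cells in clusters without a name (43.0% and 50.8% against 61.3% and 49.5%), the viability sort and the lower UMI counts per cell of ablated 1 can all set shares. Macrophages split into 10 sub-clusters and fibroblasts into 13, and 0 of each had a changed share by edgeR, with 0 and 1 at an unadjusted p under 0.05. That 1 was a fibroblast sub-cluster led by txn, vmp1, prdx1 and cxcl8b.1, with 0 and 7 cells in control 1 and 2 and 42 and 43 in ablated 1 and 2 (log2 ratio 3.29, adjusted p = 0.414). Another, led by gh1, rasl12, mcamb and EGFP, had the mural marker notch3 among its leading genes. It held 8, 24, 13 and 30 cells in the same order (log2 ratio 0.27, adjusted p = 0.959). At resolution 0.5 the sub-cluster led by gh1 and EGFP held 5, 21, 2 and 7 cells (log2 ratio -1.695, adjusted p = 0.696). The mural class itself was named on genes such as acta2, tagln and myh11a, so it need not hold all mural cells. The largest macrophage sub-cluster, led by haemoglobin genes, col2a1a and krt4 at a median of 1459 UMIs, held 196 of the 337 macrophages of control 1 and 17, 31 and 19 cells in control 2, ablated 1 and ablated 2 (log2 ratio -1.72, adjusted p = 0.854).

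**Figure D2:**
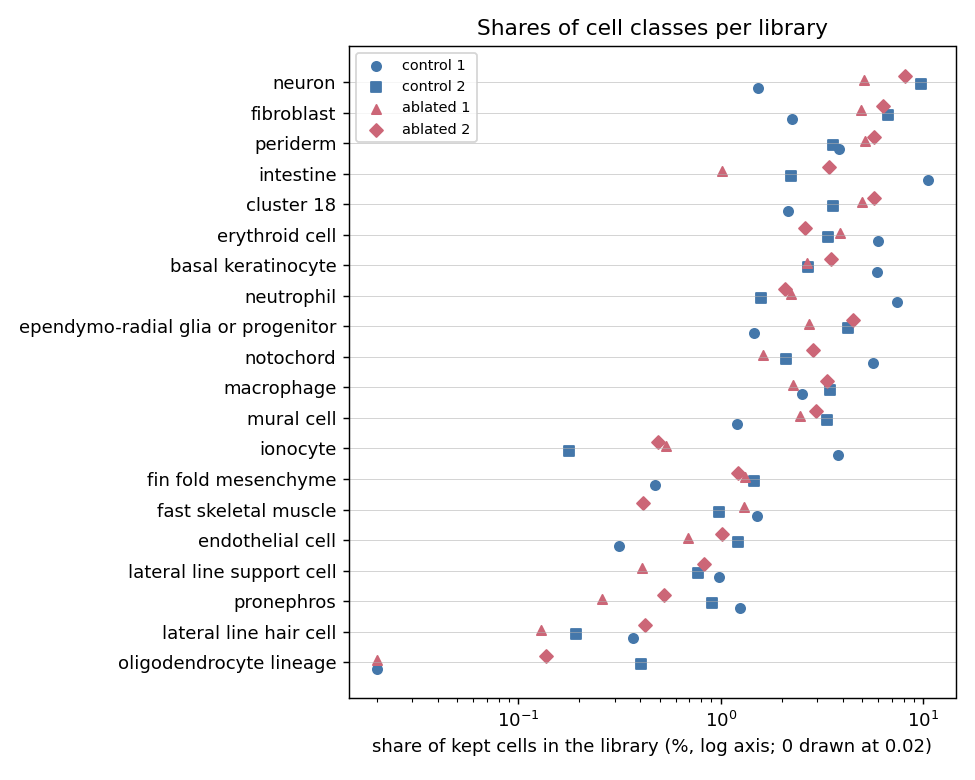
Share of each named class among the kept cells of each library, in percent on a log axis; symbols are libraries. Fibroblasts run from 2.24% in control 1 to 6.71% in control 2, with both ablated libraries between them, as do mural cells.

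In whole-tissue sums no gene of 21871 passed the threshold by edgeR, with 1093 at an unadjusted p under 0.05 where chance gives 1094, and DESeq2 called 114 genes, 58 of them higher. Leaving out control 1 gave 27 calls and leaving out control 2 gave 446; leaving out either ablated library gave 0. Among the 10 genes with the smallest p were lepb, a leptin gene, at 8.36 ± 1.32 CPM in the control and 29.8 ± 0.260 CPM in the ablated libraries (log2 1.83), and rhcgl1, an ammonium transporter gene, with a log2 change of 2.44. The hyaluronan receptor gene lyve1a had 2.39, cyr61l1 1.56, the muscle actin gene actc1a 1.40, the small heat shock gene hspb11 1.65 and slc16a9b 1.25. The 2 lower ones were cst14b.2 with -4.90 and golim4b with -1.64. The adjusted p-values of these genes were 0.730 to 0.769. The gene cst14b.2 was a leading gene of clusters 26 and 28, of which control 1 gave 114 of 114 and 120 of 174 cells. Its fall may thus rest mainly on that library.

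Within cell classes, edgeR called 229 changes in 163 genes, 92 higher and 137 lower, in 19 of the 26 classes, and 97 of the calls fell on genes with a clone or contig name. DESeq2 called 745, 169 of them shared. TMM set the median gene to no change, and with library totals the median log2 change lay higher by 0.25 in whole tissue and by up to 1.09 (cluster 11) in 25 of the 26 classes, and lower by 0.30 in fast muscle, so changes are given relative to that shift. With library totals 1363 calls were made, 1032 higher and 331 lower. Fits without 1 library set 1 library against 2 and take their spread from the group of 2 alone, so a call made in all 4 of them is no proof of stability. Of the 87 calls on named genes 30 were made in each of these fits, and the total over classes was 4509 without control 1, 12483 without control 2, 996 without ablated 1 and 703 without ablated 2.

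**Figure D3:**
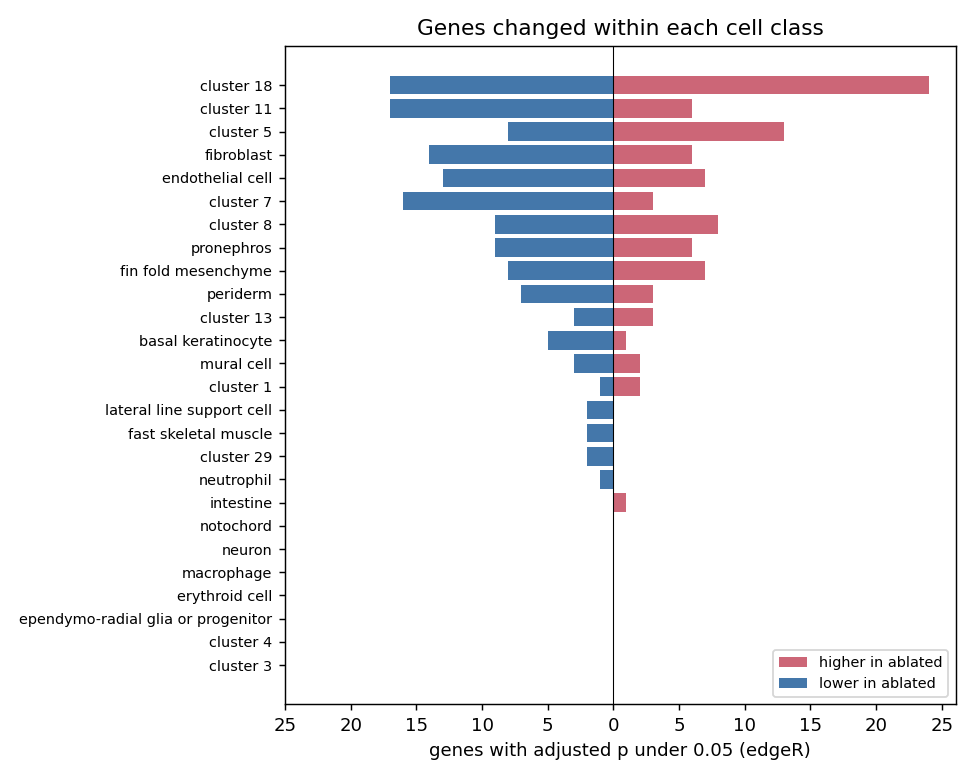
Number of genes past the threshold (edgeR, adjusted p under 0.05) in each class, higher (right) and lower (left) in the ablated libraries. Cluster 18 had 24 higher and 17 lower genes, the fibroblast class 6 and 14, and 7 classes had 0.

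In fibroblasts 6 genes were higher and 14 lower in the libraries labelled ablated. Among genes without a clone name the highest rise was in prdx1, a peroxiredoxin that removes hydrogen peroxide, from 22.2 and 55.7 CPM in control 1 and 2 to 416 and 280 CPM in ablated 1 and 2 (log2 3.10, SE 0.42, adjusted p = 0.0467). The chemokine gene cxcl8b.1, a neutrophil attractant, rose from 60.3 ± 2.65 to 474 ± 177 CPM (log2 2.97), and txn, the thioredoxin that reduces protein disulfides, from 193 ± 5.91 to 708 ± 91.9 CPM (log2 1.87). These 3 genes also led the fibroblast sub-cluster with 85 of its 92 cells in the ablated libraries, and whether they rose in the other fibroblasts was not tested. Of the 14 genes that fell, 6 were collagen genes and 4 had a locus name. The collagen genes were col9a2 with -2.625, col9a3 with -2.45, col8a1a with -2.38, col2a1a with -2.19, col11a2 with -1.98 and col9a1b with -1.87. The small leucine-rich proteoglycan genes epyc and lum fell by 2.24 and 2.11, and igsf10 by 1.99. Notochord markers measured in this class, 15 genes that include the collagen genes above and epyc, had a median log2 change of -1.87 (SD 0.77). The same markers stood at -2.51 in macrophages, -2.97 in erythroid cells and -0.36 in the notochord class itself. Fits without control 1, control 2, ablated 1 and ablated 2 called 558, 614, 20 and 16 genes, of which 20, 20, 12 and 8 were among these 20. The calls on cxcl8b.1, col9a2, col9a3 and col8a1a were made in all 4 fits, and DESeq2 called 48 genes.

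Cluster 18, the matrix-rich cells with fibroblast and tenocyte markers, had the most calls of the 26 classes, 24 higher and 17 lower. The metallothionein gene mt2, which binds zinc and copper, went from 2 to 540 UMIs over the 2 libraries of each group, 99.5 times the control level (95% counting interval 27.4 to 823). The adrenomedullin gene admb rose from 25.2 ± 10.9 to 214 ± 32.6 CPM (log2 3.10), and qdpra, a pterin reductase gene, had a log2 change of 2.92. The antioxidant gene prdx1 rose from 66.8 and 66.2 to 531 and 401 CPM (log2 2.81, SE 0.25, adjusted p = 0.00270). Also higher were sqstm1, the autophagy receptor p62, with 1.88, the apolipoprotein gene apoeb with 1.61 and phlda3, a p53 target, with 1.64. The lower genes included rn7sk, the 7SK small nuclear RNA (-2.43), the sarcoglycan gene sgcd (-1.81) and hapln1a, a hyaluronan link protein gene (-1.81). Fits without control 1, control 2, ablated 1 and ablated 2 called 737, 825, 20 and 19 genes, of which 41, 41, 14 and 16 were among these 41. The calls on mt2, admb, prdx1 and rn7sk were made in all 4 fits.

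The rise of prdx1 was found in 5 classes. Besides fibroblasts and cluster 18 these were the pronephros (522 and 751 CPM against 1734 and 1858, log2 1.497), cluster 5 (log2 1.56) and cluster 8 (log2 1.83), and its log2 change was above 0 in 25 of the 26 classes. Neutrophils, where the gene was not called, had 245 ± 62.3 and 635 ± 61.7 CPM. Without ablated 2 the pronephros call ended (adjusted p = 0.2275), and without ablated 1 or 2 that in fibroblasts did (adjusted p = 0.144 and 0.0613). In fin fold mesenchyme the antioxidant gene hmox1a, the inducible heme oxygenase, went from 2 to 93 UMIs, 26.1 times the control level (95% counting interval 7.02 to 219), and mt2 rose in cluster 5 (log2 2.63; adjusted p = 0.212 without control 2 and 0.9995 without ablated 1).

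**Figure D4:**
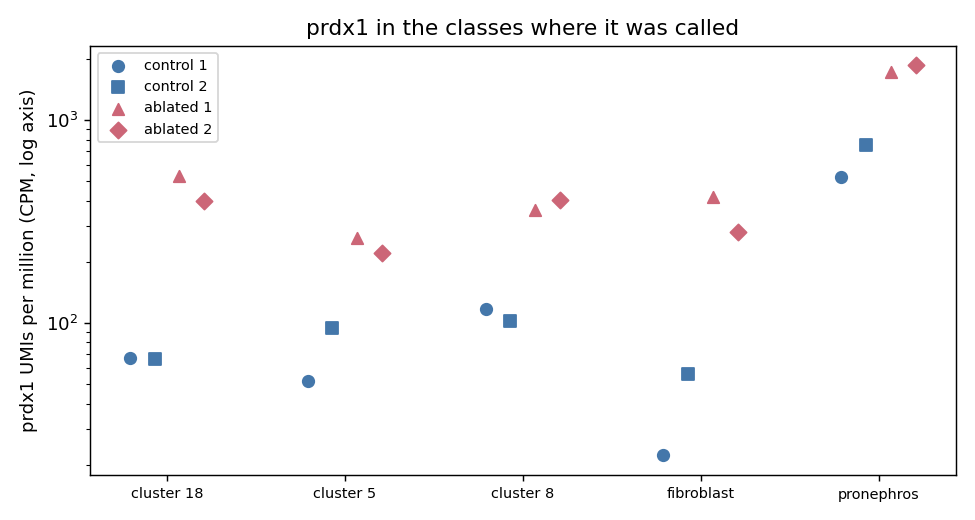
Level of prdx1 in each library (CPM on a log axis) in the 5 classes where it passed the threshold; symbols are libraries. In every class both ablated libraries lie above both control libraries, in cluster 18 at 401 and 531 against 66.2 and 66.8 CPM.

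In endothelial cells 7 genes were higher and 13 lower. The chemokine gene cxcl12b, the ligand of Cxcr4 receptors, fell from 1386 and 961 CPM in control 1 and 2 to 32.4 and 3.36 CPM in ablated 1 and 2 (log2 -5.98, SE 0.59, adjusted p = 0.00180). The transcription factor gene klf2a, which responds to blood flow, fell by 1.62, the matrix genes fbn2b and fbln2 by 2.21 and 1.55, ca16b by 2.19, the Bcl2 family gene bcl2l10 by 2.13 and rn7sk by 2.86 on the log2 scale. The gene ssuh2.1 went from 61 to 0 UMIs and was at least 15.6-fold lower. Among the rises were the water channel gene aqp1a.1 (388 ± 225 to 2821 ± 446 CPM, log2 2.805), lyve1a (392 ± 258 to 2297 ± 527.5 CPM, log2 2.62), igfbp1a (log2 1.98), the chemokine gene cxcl18a.1 (log2 2.47), swap70b (log2 2.58) and scpp8 (log2 2.29). The gene ftr69 went from 0 to 37 UMIs and was at least 16.1-fold higher. This class was named from a joint marker list for blood or lymphatic vessels and held as few as 42 cells in a library. Whether a change in the mix of vessel types set these values was not tested. Fits without control 1, control 2, ablated 1 and ablated 2 called 75, 48, 4 and 2 genes, of which 15, 13, 3 and 2 were among the 20, and of the genes named here cxcl12b alone held in all 4.

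In macrophages no gene of 11264 passed the threshold by edgeR, with 667 at an unadjusted p under 0.05 and 66 calls by DESeq2. The 10 genes with the smallest p included the transferrin gene tfa (16.3 ± 1.86 against 1.03 ± 0.398 CPM, log2 -3.95, adjusted p = 0.0624), the histone gene hist1h4l (-1.36), tnw (-1.805) and cox6b1 (-1.335). The mannose receptor gene mrc1b stood at 52.7 ± 0.276 and 105 ± 7.73 CPM (log2 0.99), aldh2.2 at log2 2.61 and dut at 1.31, while lamtor1, myofl and matn3a had -1.65, -2.61 and -1.84. Since 196 of the 337 macrophages of control 1 fell in the sub-cluster led by genes of other classes, these values compare partly different cells. Another sub-cluster led by haemoglobin genes (median 1294 UMIs) held 20, 31, 57 and 34 cells of control 1, control 2, ablated 1 and ablated 2. A sub-cluster of 187 cells had the lymphoid markers ccr9a and runx3 among its leading genes. A smaller one, of 33 cells, shared the leading genes blf, znfl2a, hdr and myb with cluster 1. The class may thus hold other cells in every library. Fits without control 1, control 2, ablated 1 and ablated 2 called 7, 78, 8 and 10 genes. Neutrophils had 1 call, on a gene with a clone name, lower (667 at an unadjusted p under 0.05, 22 calls by DESeq2), and 188, 1775, 2 and 0 calls in the same 4 fits. Of their 10 named genes, prdx1 had a log2 change of 1.37, the cytokine gene il4 1.96 and hhla2a.1 1.69. The other 7 had log2 changes below 0: anxa2a -2.06, rab42b -2.86, fgfr3 -3.51, atp1a1a.3 -3.535, alpi.1 -3.94, matn3a -2.73 and the glial gene gfap -3.30, and all 10 had an adjusted p of 0.282. Periderm markers measured in neutrophils (9 genes) had a median of -2.935, and 0.69 without control 1.

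In ependymo-radial glia and in neurons 0 genes passed the threshold by edgeR, with 700 and 849 at an unadjusted p under 0.05 and 20 and 17 calls by DESeq2. In the glia the genes with the smallest p were all at lower levels in the libraries labelled ablated. They were ptn, the growth factor pleiotrophin (199 ± 36.6 against 62.3 ± 2.40 CPM, log2 -1.67), the growth factor receptor gene fgfr2 (98.7 ± 10.7 against 35.4 ± 0.137 CPM, log2 -1.49), thbs4b (-2.05), gch2 (-3.31), the tachykinin gene tac1 (-2.95), rn7sk (-2.40), epb41b (-2.17), matn3a (-2.32) and tmie (-2.52). Of these, thbs4b, gch2, tac1 and epb41b are on the marker lists of other classes, and matn3a was a leading gene of the notochord cluster. In the glia notochord markers had a median of -1.80, haemoglobin genes -1.21, neutrophil markers -0.18 and periderm markers -0.12. Without control 1 these were -1.015, -0.32, 0.022 and 0.76, so the values may not be those of glia alone. The gene hes2.2, of a family of Notch targets, had 46 and 2 UMIs in the control and ablated libraries, a ratio of 31.3 (95% counting interval 8.19 to 266). In neurons pvalb6, a calcium buffer gene, stood at 83.4 ± 34.7 and 16.8 ± 2.06 CPM (log2 -2.38). The peptide genes uts2d and sst6 had 1.73 and 2.67, esm1 1.52 and the transcription factor gene runx3 2.92, while col11a1a had -1.90, nxph1 -1.99, nsmfa -1.53 and mpp1 -1.501. The neuron class pooled clusters 0, 23 and 33 (1709, 161 and 192 cells), and esm1 was a leading gene of cluster 23. Whether a change in the mix of these clusters set such values was not tested. The channel gene trpc4a had 1 and 67 UMIs, a ratio of 42.5 (95% counting interval 7.36 to 1702). The smallest adjusted p was 0.233 in the glia and 0.0959 in neurons. Fits without control 1, control 2, ablated 1 and ablated 2 called 33, 224, 149 and 80 genes in the glia and 189, 147, 107 and 26 in neurons.

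In the skin, basal keratinocytes had 1 gene higher and 5 lower. The leptin gene lepb rose from 11.2 and 14.6 CPM in control 1 and 2 to 74.5 and 60.5 CPM in ablated 1 and 2 (log2 2.405, SE 0.28, adjusted p = 0.0397). Of the lower genes fcer1gl, a signalling adaptor of immune cells, fell by 3.38 on the log2 scale, and the chemokine gene ccl20a.3 went from 54 to 2 UMIs, 26.4 times lower (95% counting interval 6.96 to 223). None of these 3 calls held without ablated 1 or without ablated 2 (0 genes called in either), and without control 1 or 2 there were 205 and 1070 calls with all 6 among them. The keratin gene krt97 had 93.0 ± 6.70 and 322 ± 2.81 CPM, csf3b, a granulocyte growth factor, a log2 change of 2.26, gldc 2.24, slc43a2b 2.97, anxa3a -3.61, the leukocyte gene coro1a -2.78 and tgfbi -1.94, none past the threshold. In periderm, 3 genes were higher and 7 lower. The ammonium transporter gene rhcgl1 rose from 23.3 ± 12.7 to 197 ± 22.9 CPM (log2 3.14) and znf652 by 2.39, while hist1h4l fell by 2.70 and pkhd1l1 by 2.29. Fits without the 4 libraries in the same order called 78, 698, 5 and 46 genes, of which 9, 10, 2 and 9 were among the 10.

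Among the other mesenchymal classes, fin fold mesenchyme had 7 higher and 8 lower genes, with mmp9, a gelatinase gene induced by injury, at log2 3.62 and cib1 at 2.57, and with clu (clusterin), rn7sk and gapdh down by 3.02, 2.95 and 2.75. Without control 1 the call on clu ended (adjusted p = 0.143), as did that on gapdh without control 2 (0.362) and without ablated 1 (0.0710) and that on cib1 without ablated 1 (0.112). Mural cells had 2 higher and 3 lower genes. The apolipoprotein gene apoc1 had 0 UMIs in the control libraries and 209 in the ablated ones, at least 51.6-fold higher, aanat2 rose from 6.59 ± 3.34 to 80.6 ± 11.98 CPM (log2 3.74), and col17a1a, a collagen of basal keratinocytes, fell by 4.54. These 3 calls were made in all 4 fits without 1 library. The pronephros, with as few as 28 cells in a library, had 6 higher and 9 lower genes. The keratin gene krt15 rose (log2 3.49), as did noxo1b, a subunit gene of NADPH oxidase (log2 1.68; adjusted p = 0.0832 without ablated 1 and 0.0833 without ablated 2). The haemoglobin genes hbae1.3 and hbbe2 fell by 4.104 and 3.47 and hist1h4l by 3.75, and the 8 haemoglobin genes measured there had a median of -3.37.

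Clusters without a name were tested by number. Cluster 5, the largest and shallowest (a median of 673 UMIs), held 120 cells of control 1 and 1903, 4391 and 1879 of control 2, ablated 1 and ablated 2. It had 13 higher and 8 lower genes, with the adrenomedullin gene adma at 2.05, the metalloproteinase inhibitor gene timp2b at 1.81 and ndufa13 at 1.75. The interferon regulatory factor gene irf1b was at -1.84, rn7sk at -2.15 and hist1h4l at -1.89. In the fits without control 1, control 2, ablated 1 and ablated 2, 21, 8, 4 and 7 of its 21 calls were kept. Cluster 7, led by mmp13a and itln1 with 6 neutrophil markers, had 3 higher and 16 lower genes, with vdac1 at 2.98, noctb (nocturnin, a circadian gene) at 2.565, the transporter gene abcb4 at -3.32, hist1h4l at -2.79 and hist2h3c at -2.39, and kept 16, 18, 19 and 18 of 19. Cluster 8, led by gcga and ccl25b, had 8 higher and 9 lower genes. Its interferon-induced gene ifitm1 rose from 174 ± 81.5 to 1572 ± 886 CPM (log2 3.09) and agrp by 3.01 and adma by 1.91, while dhrs3b (-2.80), col2a1a (-2.225) and rn7sk (-2.16) fell, and it kept 15, 12, 7 and 4 of 17. Cluster 11 had 6 higher and 17 lower genes, among them ccl20a.3 (-2.59), plekhs1 (-2.49), rn7sk (-2.12) and the lysosomal gene hexb (-1.86), and kept 2, 18, 14 and 8 of 23. Cluster 13 held 11 markers of fast muscle and 4 of slow muscle among its leading genes. It had no name because slow muscle had at least as many markers among its 10 leading genes. There cxcl8b.1 rose by 2.91 and rn7sk fell by 2.40. In cluster 29 the disulfide isomerase gene pdia2 fell by 3.77, a call not made without ablated 1. The collagen gene col2a1a fell by 3.17 in lateral line support cells (adjusted p = 0.788 without ablated 2).

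Some RNAs moved one way in all classes. The 7SK RNA rn7sk was called lower in 8 classes and lay below 0 in 26 of 26 (median -2.80, from -3.81 to -1.81), col2a1a was called lower in 5 and lay below 0 in 26 of 26, and the histone gene hist1h4l was called lower in 4 and lay below 0 in 26 of 26. The locus zgc:158463 took 15.7% and 22.0% of UMIs in control 1 and 2 and 6.29% and 3.84% in ablated 1 and 2, and LOC110438439 took 1.99%, 1.97%, 0.999% and 0.704%. With both loci left out of the sums, an alternative chosen after the data were seen, 195 calls were made within classes.

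Of the 533 tests of the fixed gene lists, 100 passed the threshold by camera with the preset correlation, 34 up and 66 down. With an estimated correlation 0 of them did (adjusted p = 0.979 for each), and fry called 0. Both measure the spread between libraries, with the few degrees of freedom that 2 libraries per group leave. Their power over 533 tests was not measured and may be small, so their 0 calls do not tell lists with a firm change from others. The calls with the preset correlation rest on that assumed value, so they do not show changes beyond the spread between libraries. In the fits without 1 library, 27 of the 100 were called in the same direction in all 4. Under library totals the median of 12 of the 100 changed sign, which follows from the shift that totals add to all genes of a class, and under RLE factors that of 0.

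**Figure D5:**
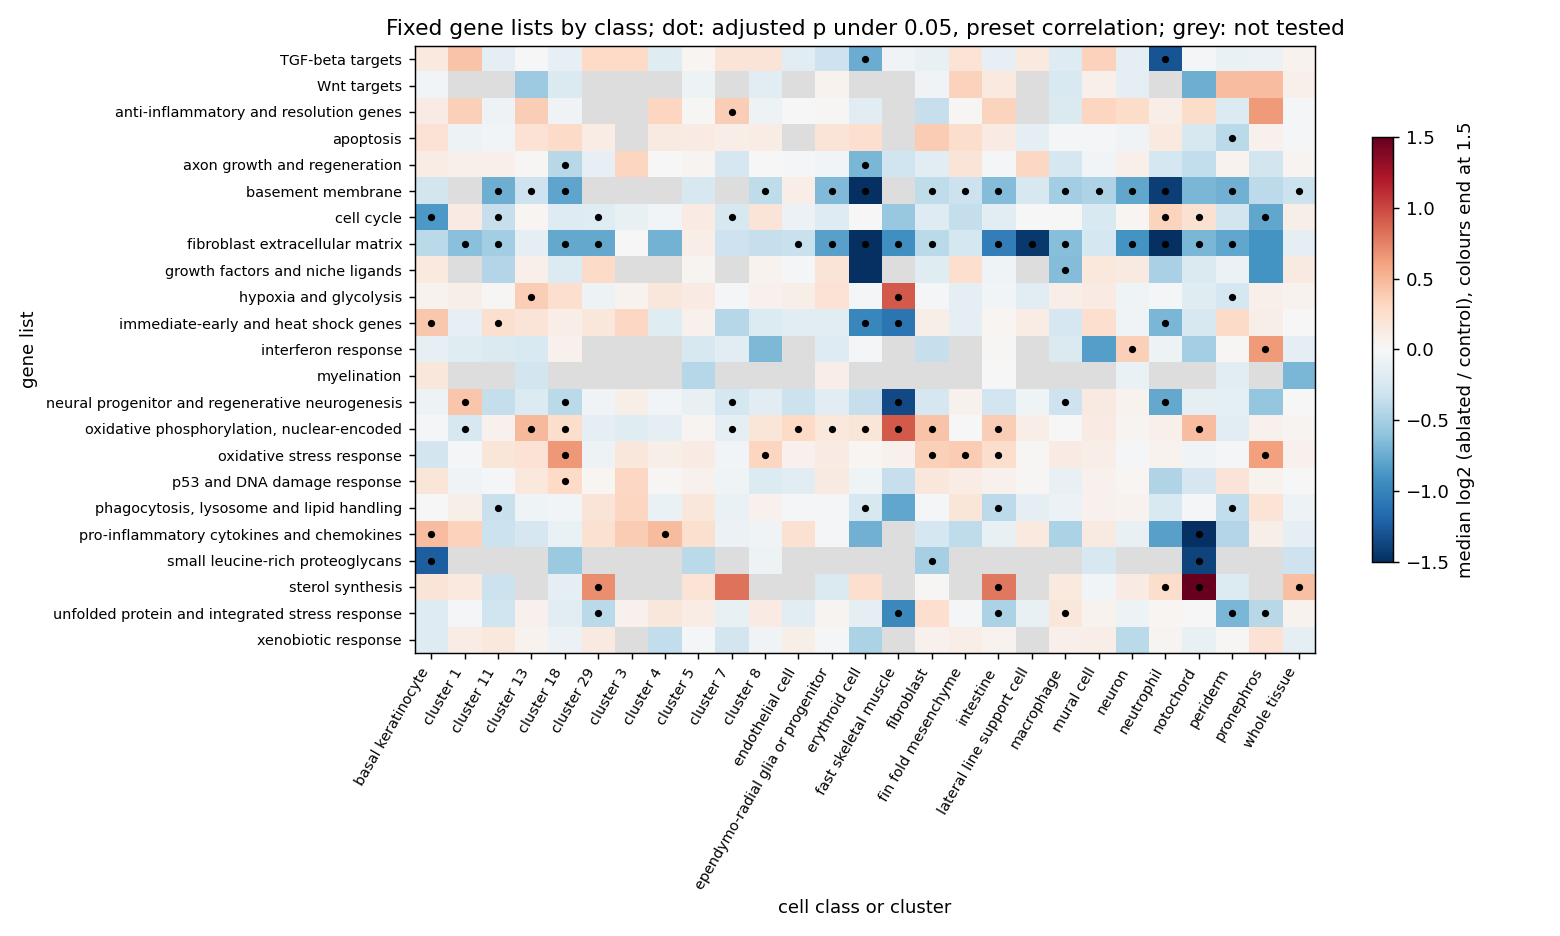
Median log2 change of each fixed gene list (vertical axis) in each class and in whole tissue (horizontal axis), with red for higher in the ablated libraries and blue for lower; dots mark adjusted p under 0.05 by camera with the preset correlation, and grey marks lists with too few members. The oxidative stress list has its highest median, 0.66, in cluster 18, and the matrix lists are blue in most classes.

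Oxidative stress genes rose in 6 of 27 tests and fell in 0, each with an adjusted p of 0.979 at an estimated correlation. In cluster 18 the list of glutathione, thioredoxin and peroxiredoxin genes had a median log2 change of 0.66 over 27 members (adjusted p = 2.7e-06), 23 of them above 0. Of these members 4 passed over all genes, among them prdx1, mt2 and sqstm1, and 11 passed adjusted over the list alone. The list rose also in the pronephros (0.62), fibroblasts (0.35; 2 members passed, prdx1 and txn, and 5 adjusted over the list alone), fin fold mesenchyme (0.38), cluster 8 (0.32) and the intestine (0.26). The calls in cluster 18, the pronephros and fibroblasts were made in all 4 fits without 1 library (highest adjusted p 0.000558, 0.02185 and 0.0430). Those in the others ended without control 1 (fin fold, 0.0876) or control 2 (cluster 8, 0.205; intestine, 0.188). The p53 and DNA damage list rose in 1 of 27 tests, cluster 18 (median 0.30, adjusted p = 0.00465; 0.979 at an estimated correlation), where phlda3 was the named member past the threshold, and this ended without control 1 (0.05375). Apoptosis genes fell in 1 of 24 tests, the periderm (median -0.41, adjusted p = 0.00725; 0.979 at an estimated correlation, 0.0769 without control 1 and 0.0793 without ablated 2). Of its members bcl2l10, lower in endothelial cells, passed over all genes. The xenobiotic list, which holds targets of the aryl hydrocarbon receptor, changed in 0 of 24 tests, with abcb4 in cluster 7 as its 1 member past the threshold.

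Extracellular matrix genes fell in 16 of 27 tests and rose in 0, and each matrix call below had an adjusted p of 0.979 with an estimated correlation. The fibroblast matrix list had a median log2 change of -0.76 in cluster 18 (31 members, 28 below 0, 18 passing adjusted over the list alone, adjusted p = 1.3e-06), -0.41 in fibroblasts (36 members, adjusted p = 0.0116), -2.45 in erythroid cells and -1.94 in neutrophils, the last 2 being classes that should lack such genes. Neutrophil markers in erythroid cells had a median of -2.185 and periderm markers -2.58, and without control 1 they had 0.40 and 1.36. Genes of other cells were also lower in cluster 18: haemoglobin genes -1.46, neutrophil markers -0.93, periderm markers -0.89 and notochord markers -1.75. Leaving out control 1 gave -0.69, -0.11, 0.26 and -1.29 there, and -0.55 for the matrix list. How much of the matrix fall in cluster 18 lay in its own cells was not tested. Of the 16 calls 6 were made in all 4 fits without 1 library, among them cluster 18, erythroid cells, neutrophils and periderm, while that in fibroblasts ended without control 2 (0.0833) and without ablated 2 (0.107). Of its members fbn2b and fbln2 in endothelial cells and timp2b, which rose in cluster 5, passed over all genes. With library totals the median turned positive in endothelial cells (0.39) and cluster 11 (0.50). Basement membrane genes fell in 15 of 21 tests, with -0.79 in cluster 18 (17 of 17 members below 0, adjusted p = 1.8e-06) and -0.32 in whole tissue (adjusted p = 0.00357, and 0.358 without control 2), and 5 of these calls were made in all 4 fits; its median turned positive with library totals in clusters 8 and 11, fibroblasts and fin fold mesenchyme. Of its members col17a1a, lower in mural cells, passed over all genes. Small leucine-rich proteoglycan genes fell in 3 of 8 tests: basal keratinocytes (-1.24), fibroblasts (-0.50, adjusted p = 0.00420), where epyc and lum passed over all genes, and the notochord (-1.39; adjusted p = 0.1295, 0.142 and 0.0724 without control 1, control 2 and ablated 1). TGF-beta targets fell in 2 of 27 tests, erythroid cells (-0.74) and neutrophils (-1.30), and both calls ended without control 1 (0.856 and 0.814) and without ablated 1 (0.211 and 0.219); no member passed, and ctgfa stood at 491.5 ± 158 and 190.5 ± 3.06 CPM in fibroblasts.

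Lists of energy and lipid metabolism were called in several classes with the preset correlation, with an adjusted p of 0.979 for each at an estimated correlation and 0 members of oxidative phosphorylation and sterol synthesis past the threshold over all genes. Nuclear genes of oxidative phosphorylation, which encode the respiratory chain, rose in 9 of 27 tests and fell in 2. The highest median was that of fast muscle, 0.92 (47 of 47 members above 0, adjusted p = 1.2e-13). It was 0.49 in cluster 13, where cox7a1 stood at 9.06 ± 3.26 and 43.3 ± 11.5 CPM, 0.46 in the notochord and 0.425 in fibroblasts, and these 4 calls were made in all 4 fits without 1 library. Fast muscle markers were higher too, with a median log2 change of 0.91 in fast muscle (30 genes) and 1.73 in cluster 13 (31 genes). In fast muscle, with as few as 33 cells in a library, neutrophil markers had -1.88, periderm markers -2.51 and notochord markers -1.58. Whether list changes in these muscle classes went beyond a change in how much of each sum came from muscle was not tested. Sterol synthesis genes rose in 5 of 18 tests and fell in 0. In the notochord their median log2 change was 1.91 (23 members, 16 passing adjusted over the list alone, adjusted p = 3.6e-09), with fdps, farnesyl diphosphate synthase, at 24.8 ± 9.16 and 124 ± 41.4 CPM and tm7sf2 at 8.22 ± 2.12 and 35.5 ± 4.86 CPM, and in whole tissue it was 0.45 (22 of 25 members above 0, adjusted p = 1.8e-06). Both calls were made in all 4 fits, while those in the intestine (0.79), cluster 29 (0.70) and neutrophils (0.26) ended without control 1 (0.113, 0.290 and 0.194). Hypoxia and glycolysis genes rose in 2 of 27 tests, cluster 13 (0.37) and fast muscle (0.92), and fell in 1, the periderm (-0.26, and 0.021 with library totals). All 3 ended without control 1 (0.116, 0.0945 and 0.1765), and of the members igfbp1a and adma rose and gapdh fell in other classes.

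Lists of inflammation moved in few classes, and none did with an estimated correlation (adjusted p = 0.979). Pro-inflammatory genes rose in 2 of 26 tests, basal keratinocytes (median 0.46, adjusted p = 0.0168; 0.776 without control 1) and cluster 4 (0.47; 0.0631, 0.117 and 0.456 without control 1, control 2 and ablated 2), and fell in 1, the notochord (-1.51, adjusted p = 0.0405, called in all 4 fits without 1 library). The chemokine genes cxcl8b.1, higher in fibroblasts and cluster 13, and ccl20a.3, lower in basal keratinocytes and clusters 5 and 11, were the members past the threshold. Anti-inflammatory genes rose in 1 of 23 tests, cluster 7 (0.37, adjusted p = 0.0216; 0.0857 without control 1 and 0.0953 without control 2), where il4 stood at 97.0 ± 24.6 and 294 ± 55.3 CPM; arg2 stood at 3.32 ± 0.00525 and 14.4 ± 1.17 CPM in cluster 1. Phagocytosis and lysosome genes fell in 4 of 27 tests, the intestine (-0.40, and 0.034 with library totals), erythroid cells (-0.24), periderm (-0.37) and cluster 11 (-0.33, and 0.86 with library totals), and 0 of these calls were made in all 4 fits; of their members apoeb and sqstm1 rose in cluster 18, apoc1 in mural cells, and hexb fell in cluster 11. Interferon genes rose in 2 of 20 tests, neurons (0.36; 0.0906 without ablated 1) and the pronephros (0.64; 0.476, 0.328, 0.0738 and 0.831 without control 1, control 2, ablated 1 and ablated 2), and irf1b, lower in cluster 5, was the member past the threshold.

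Among lists of growth and repair, again with adjusted p = 0.979 at an estimated correlation, cell cycle genes fell in 5 of 27 tests and rose in 2. Their median log2 change was -0.86 in basal keratinocytes (35 of 37 members below 0, adjusted p = 2.4e-08; 0.179 without control 1), -0.78 in the pronephros and 0.33 in neutrophils (39 of 43 above 0), the last 2 called in all 4 fits, and ube2c stood at 19.3 ± 0.489 and 4.69 ± 1.78 CPM in the periderm. Neural progenitor genes fell in 5 of 27 tests and rose in 1, with -1.36 in fast muscle, -0.77 in neutrophils, -0.40 in cluster 18, -0.32 in macrophages, -0.27 in cluster 7 and 0.42 in cluster 1, and were not called in ependymo-radial glia or neurons, where lin28a stood at 23.5 ± 12.7 and 69.8 ± 9.74 CPM in neurons. Axon growth genes fell in 2 of 27 tests, cluster 18 (-0.41; 0.0953 without control 2) and erythroid cells (-0.685), with plxna3 at 37.4 ± 3.72 and 15.6 ± 0.114 CPM in cluster 18 and alcamb at 63.1 ± 11.8 and 144 ± 11.96 CPM in neurons. Growth factor genes fell in 1 of 21 tests, macrophages (-0.65; 0.571 without control 1), and cxcl12a rose in cluster 5 (log2 1.503) while cxcl12b fell in endothelial cells. None of the neural progenitor, axon growth and growth factor calls were made in all 4 fits without 1 library. Myelination genes changed in 0 of 8 tests, with sox10 at 19 and 3 UMIs in the notochord and nrg1 at 142 ± 31.2 and 66.5 ± 1.12 CPM in cluster 11, and Wnt targets in 0 of 16, with notum1a at 41.5 ± 3.74 and 8.86 ± 2.61 CPM in cluster 8 and notum1b at 1.64 ± 0.265 and 8.56 ± 2.05 CPM in cluster 18.

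Stress lists other than the antioxidant one went both ways, with adjusted p = 0.979 for each at an estimated correlation. Immediate-early and heat shock genes rose in 2 of 27 tests, basal keratinocytes (0.41; 0.125 without control 1 and 0.162 without ablated 2) and cluster 11 (0.24; 0.0887, 0.246 and 0.838 without control 1, control 2 and ablated 2). They fell in 3, fast muscle (-1.09, called in all 4 fits), erythroid cells (-0.98) and neutrophils (-0.68). Without control 1 the direction turned to up in erythroid cells (0.856) and neutrophils (0.260, and 0.666 without ablated 1). The member past the threshold was klf2a, in endothelial cells. Unfolded protein response genes fell in 5 of 27 tests and rose in 1. The periderm had a median of -0.69 (adjusted p = 0.000325, called in all 4 fits), with dnajb9b at 9.89 ± 3.07 and 1.75 ± 0.136 CPM and the chaperone gene calr3b at 160 ± 24.8 and 57.7 ± 11.97 CPM. The calls in the intestine (-0.47), fast muscle (-0.97), pronephros (-0.41), cluster 29 (-0.41) and macrophages (0.16, up) did not hold without control 2 (adjusted p = 0.251, 0.0984, 0.390, 0.593 and 0.285).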

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

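All tests of explanations in this section were chosen only after the results had been seen. Several results call for a second look, and differences between classes given here were not tested.

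The EGFP entry of the feature list, which the labels do not mention, stood at 94.9 CPM in the ablated libraries (SD 13.5) and 36.7 CPM in the control libraries (SD 17.6). In cluster 18 it stood at 261 and 49.3 CPM in control 1 and 2 and at 841 and 684 CPM in ablated 1 and 2. Cells with an EGFP UMI made up 9.61%, 4.65%, 12.4% and 9.45% of all cells in control 1, control 2, ablated 1 and ablated 2, and 9.45%, 4.87%, 10.6% and 10.5% of erythroid cells. Erythroid cells of control 2, ablated 1 and ablated 2 were far deeper than other cells. Their EGFP level was lower, at 14.4, 2.22, 3.89 and 3.84 CPM in the 4 libraries against 49.2, 24.3, 104 and 85.3 CPM over all cells. A UMI alone thus does not mark a deep cell as carrying EGFP, and outside control 1 the erythroid shares overstate the background of shallower cells.

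Some gene lists had opposite signs in 2 classes, given here as mean log2 changes. Pro-inflammatory genes stood at 0.78 in cluster 4 and -1.01 in the notochord, 1.79 apart, and immediate-early and heat shock genes at 0.36 in basal keratinocytes and -1.01 in fast muscle, 1.375 apart. Unfolded protein response genes stood at 0.21 in macrophages and -0.55 in periderm, 0.760 apart. Cell cycle genes stood at 0.38 in neutrophils and -0.70 in basal keratinocytes, 1.08 apart, neural progenitor genes at 0.52 in cluster 1 and -0.93 in neutrophils, 1.45 apart, and hypoxia genes at 0.55 in cluster 13 and -0.30 in periderm, 0.851 apart. These differences were not tested.

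Oxidative stress genes were called higher in cluster 18 and fibroblasts with the preset correlation (adjusted p = 0.979 at an estimated correlation, and not called by fry), while mural cells, with the second highest pdgfrb level (83.5 CPM), had a median of 0.10. A shift shared by whole libraries would move the list in all classes. The list's median over the 13 classes with the lowest pdgfrb levels was 0.0534 (SD 0.208) against 0.66 in cluster 18. This argues against such a shift for cluster 18, although the pronephros, one of the 13, had 0.62. Fibroblasts had 0.35, too close to that spread to decide, and prdx1 and txn lay above 0 in 25 and 23 of the 26 classes. The drug acting on cells that carry the transgene could raise the list in cells with an EGFP UMI: in cluster 18 their log2 ratio to other cells was 0.44 and 0.75 in control 1 and 2 and 0.87 and 1.09 in ablated 1 and 2, a gap of 0.121. That cannot be decided, since it is not known whether EGFP marks the transgene. The cells with an EGFP UMI were also deeper, with medians of 3511, 8450, 5680 and 6413.5 UMIs in control 1, control 2, ablated 1 and ablated 2. The other cells of cluster 18 had 1981, 2760, 2244 and 2354, so the ratio compares deep with shallow cells. In control 1 background EGFP was common, with a UMI in 9.45% of erythroid cells. Reporter reads, for mCherry or the nitroreductase, would tell.

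Matrix genes were lower in erythroid cells and neutrophils, which should lack them. Free RNA in the shallow barcodes of control 1 may explain this, since the median in erythroid cells went from -2.45 to -0.506 without control 1. Lower expression by the source cells alone stays open: neutrophil and periderm markers also had a median of -2.29 (SD 1.09, 27 markers) in erythroid cells, but without control 1 they had 0.40 and 1.36 while the matrix list was still called lower with the preset correlation (adjusted p = 0.0176), a kind of call that neither an estimated correlation nor fry made with all 4 libraries. That a marker test has to hold without control 1 was added after both values had been seen. The fall of collagen genes in fibroblasts could share this source in part. Those collagen genes are themselves on the notochord marker list, so the median of that list there, -1.65 without control 1, cannot decide it. In other classes, also without control 1, that list had -1.29 (macrophages), -1.275 (neutrophils), 0.35 (intestine) and 0.79 (endothelial cells).

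The RNAs rn7sk and zgc:158463 were lower in every class. A difference between libraries in how much of such RNA was captured would give this, with both below 0 in 26 of 26 classes, but it cannot be told from an effect of the treatment because library and group go together. Control 1 alone does not explain it, since zgc:158463 had a log2 change of -2.36 (SE 0.542) in whole tissue without control 1 and -2.18 with it.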

How the results depend on the processing

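The whole-tissue count of 0 genes became 114 with DESeq2 and 0 to 446 when 1 library was left out. The log2 change of pdgfrb turned to 0.14 with library totals and to 0.0027 without ablated 2, within -0.32 to 0.17 with 1 library left out (0.17 without control 2). With library totals the median log2 change over all genes of whole tissue lay higher by 0.25, and the sign of pdgfrb there follows from that shift. The cause was not tested for the other changes.

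Within classes the total of 229 became 745 with DESeq2, 5461 without a filter on low counts, 1363 with library totals, 125 with edgeR without robust estimation and 703 to 12483 with 1 library left out. Macrophages went from 0 to 66 (DESeq2), 308 (no filter), 7 to 78 (1 library left out), 1 (no doublet removal) and 1 (stricter cell filter). Neutrophils went from 1 to 22 (DESeq2), 441 (no filter) and 0 to 1775 (1 library left out), and to 0 with RLE factors, no doublet removal, the stricter cell filter, the 2 loci left out, library totals, or no robust estimation. Fibroblasts went from 20 to 48 (DESeq2), 468 (no filter), 497 (library totals) and 16 to 614 (1 library left out). Ependymo-radial glia went from 0 to 20 (DESeq2), 167 (no filter), 1 (library totals) and 33 to 224 (1 library left out). Neurons went from 0 to 17 (DESeq2), 140 (no filter), 15 (no doublet removal), 1 (library totals) and 26 to 189 (1 library left out).

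Basal keratinocytes went from 6 to 46 (DESeq2), 345 (no filter), 19 (library totals), 0 (no doublet removal), 0 (no robust estimation) and 0 to 1070 (1 library left out). Endothelial cells went from 20 to 12 (DESeq2), 54 (no filter), 58 (library totals), 12 (no robust estimation) and 2 to 75 (1 library left out). Cluster 18 went from 41 to 90 (DESeq2), 558 (no filter) and 19 to 825 (1 library left out). Of the 87 calls on named genes, DESeq2 kept 69, RLE factors 85, library totals 71, and no robust estimation 50. No doublet removal kept 65 and lost 21, and the stricter cell filter kept 55 and lost 23, with the rest untested because the class or the gene was not fitted there (22 and 23 of the 26 classes were fitted).

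With the replicate number as a block the counts were 1673 in all classes, 20 in macrophages, 69 in neutrophils, 241 in fibroblasts, 71 in neurons, 0 in basal keratinocytes, 43 in endothelial cells and 165 in cluster 18, and 94 of the 100 list calls were kept. The correlation of deviations between libraries of the same number was 0.0912 in whole tissue and -0.152 to 0.326 over classes. With only 2 pairs this cannot settle whether the numbers pair libraries, and since the labels do not say that they do, no block was used.

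The number of classes with a changed share went from 0 to 1 without doublet removal and to 0 to 6 with 1 library left out. Without control 1 the log2 ratio of the share turned to -0.25 in fibroblasts, -0.30 in mural cells and 0.45 in neutrophils, and without control 2 it was 1.33, 1.17 and -1.78. In macrophages it turned to 0.15 without control 2, 0.17 without ablated 1 (-0.40 without ablated 2), 0.0075 without doublet removal and 0.51 with the stricter cell filter. Of the 100 lists, 0 were called with an estimated correlation and 0 by fry. The direction of oxidative phosphorylation genes turned in cluster 7 without ablated 2 (adjusted p 0.958, lowest 0.000133 without ablated 1), endothelial cells without ablated 1 (0.993, lowest 0.00124), ependymo-radial glia without control 2 (0.606, lowest 4.0e-05) and the intestine without control 2 (0.978, lowest 7.0e-10). The same held for immediate-early and heat shock genes without control 1 in erythroid cells (0.856, lowest 9.8e-07) and neutrophils (0.260; 2.7e-05 to 0.666 over the 4 fits), and without ablated 2 for matrix genes in fast muscle (0.967, lowest 0.00336) and interferon genes in the pronephros (0.831, lowest 0.07385).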

Other observations

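The test given here was chosen only after the result had been seen, and its rule was reworded once 2 UMIs of gh1 had been counted in control 1, where it had first been written for 0.

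The growth hormone gene gh1, which is made in the pituitary and not in the trunk, was found with 2, 797, 1349 and 847 UMIs in control 1, control 2, ablated 1 and ablated 2. Over all cells, most with gh1 had no EGFP UMI: 182 of 238 in control 2, 209 of 323 in ablated 1 and 117 of 186 in ablated 2. In cluster 18, 8 of 21 cells with an EGFP UMI had a gh1 UMI in control 2, 57 of 211 in ablated 1 and 36 of 124 in ablated 2 (odds ratios 14.4, 8.997 and 22.3), and 0 of 59 in control 1. Of the cells with gh1 in cluster 18, 8 of 17 in control 2, 57 of 70 in ablated 1 and 36 of 42 in ablated 2 had an EGFP UMI, and in fibroblasts 19 of 34, 5 of 16 and 11 of 20 (odds ratios 20.7, 1.99 and 7.30). Cells with an EGFP UMI were deeper than the others in both classes, which can raise these odds ratios. An EGFP UMI was also found in 4.87% to 10.6% of erythroid cells, at 2.22 to 14.4 CPM against 49.3 to 841 CPM in cluster 18. Those of control 2, ablated 1 and ablated 2 were far deeper than cells of cluster 18. Within fibroblasts gh1 and EGFP were both leading genes of the same sub-cluster, of 75 cells. EGFP had been left out of the genes used to form it, while gh1 had not. Over all cells there were 0.0820, 80.1, 21.8 and 20.2 gh1 UMIs per 100 of EGFP in control 1, control 2, ablated 1 and ablated 2. If both came from 1 transcript in every library, for instance a transgene with a growth hormone sequence, control 1 would hold at least 491.5 gh1 UMIs, and it held 2, which argues against that. The EGFP of control 1 could thus come from another source than that of the other 3 libraries.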
